A study of Mus musculus with 6 samples.

How the data were processed

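RNA of isolated mouse collecting duct cells was measured in 6 libraries, 3 from mice on a low-NaCl and 3 from mice on a high-NaCl diet. The deposited files hold raw read counts, 1 file per library. Per the file headers, the authors counted reads with featureCounts 1.5.0-p3 over exons of a UCSC annotation of build mm10, with no option for strand or overlap. By that program's defaults strand is then ignored, and a read that overlaps more than 1 identifier is not counted. The submitters' processing notes also name FastQC, Subread and edgeR without versions, and the aligner and trimming are not given in the sources used here. The deposited identifiers are 59121 UCSC transcripts, not genes, so reads in exons shared by isoforms were not counted. Overlapping genes on opposite strands cannot be told apart.

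The samples, tests, most alternatives, 36 gene lists and the rule for naming genes were chosen before the data were examined, on the assumption that counts were per gene. The choice to sum transcripts per gene was made once the identifiers were seen and before any test. Each identifier was matched to a gene of GENCODE by identical introns (41510 identifiers, 72.2% of counts) or else by an overlap of at least 50% of exonic bases (11061, 22.2%), and summed to 24902 genes. The 6550 unmatched identifiers (5.57% of counts) entered library sizes only. The countable share of a gene is the share of its exonic bases in exons of a single identifier. It says nothing of reads that map to several places: Gapdh, 100.0% countable, measured 6.06 ± 0.658 against 6.65 ± 1.04 CPM. A loss of such reads was not tested, so CPM values of fully countable genes may be incomplete too. The countable share was under 50% in 32.3% of the tested genes and in 44 of the 366 called ones. Of called genes named below, it was 12.1% for Adgrf5, 13.8% for Car12, 17.9% for Cdkn1a and 24.5% for Slc12a1. It was 30.8% for Ptger1, 37.5% for Rasl11a, 37.8% for Sec14l1 and 43.6% for Junb.

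Genes were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, Python 3.11.15). Library size was the total of all counts, low counts were removed with filterByExpr by diet, factors were TMM, and glmQLFit with robust estimation and glmQLFTest compared the diets without covariates. The SE is the absolute log2 fold change divided by the square root of the F statistic. P-values were adjusted by Benjamini-Hochberg over 10562 genes, with a threshold of 0.05. The biological coefficient of variation was 21.6%. Lists fixed beforehand with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over 35 lists. At that setting 15 lists passed, 9 higher and 6 lower. With an estimated correlation camera passed 0, with 7 at an unadjusted p under 0.05, and fry, which tests whether a list moves on balance, passed 5. Those 5 were the aldosterone target, principal cell, connecting tubule, immediate early and unfolded protein response lists. The shared, type A and type B intercalated lists did not pass fry (adjusted p = 0.141, 0.157 and 0.0664).

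Genes named were 8 genes of sodium transport and mineralocorticoid action in any case, the 10 higher and 10 lower genes with the smallest p among called genes with a mean log2 CPM of at least 1, separated diets and no placeholder symbol or pseudogene, and up to 4 members of each list by smallest p. Gapdh, Ier3, Rhcg, Rhbg and the members of 4 later lists (tubulins, macula densa, antigen presentation and Notch signalling) were named after their values were seen. The camera p-values of these 4 lists were adjusted over the 4 alone. An exploratory look at all lists and leading genes came before those later lists and before the tests of explanations, whose bounds were revised after earlier runs, those for lane and for a loss of principal cells last.

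On simulated counts of 10406 genes with 100 changed 2-fold and 100 changed 4-fold, the procedure recovered 66% and 98% of them, 7.34% of its 177 calls were false, and camera called 2 of 2 raised and 0 of 20 unchanged lists. The simulated genes varied independently of each other. The list result therefore does not test the preset correlation on lists whose members vary together. Replicates differed by a chi-square per degree of freedom of 38.1 to 244, so none was a duplicate. Depth was 40101900 to 46861500 counts per library, and the precision of a gene depends on it and on the countable share.

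Alternatives chosen beforehand were median-ratio, upper-quartile and total-count scaling, no filter, a filter of CPM of at least 1 in at least 3 samples, DESeq2 1.42.0, limma-voom with and without sample weights, the fit without robust estimation, the replicate number as a block, lane as a term, and leaving out each library. Chosen after the data were seen were each transcript alone, exact intron matches only, only genes at least 50% countable, and leaving out libraries with over 25% mitochondrial counts. Lanes were read from the file headers.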

Results

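RNA was sequenced from collecting duct cells isolated from the kidneys of male C57BL/6J mice, an inbred strain, after 5 days on either of 2 diets. The collecting duct is the last part of the kidney tubule, where aldosterone, a steroid hormone released when sodium intake is low, raises the uptake of sodium from urine. The low-NaCl diet held 0.01 to 0.02% sodium and the high-NaCl diet 2.4% sodium, with 3 libraries per diet. The labels do not say how the cells were isolated, nor whether each library came from its own animal, so the p-values measure the spread between these libraries, which may be technical. The low-NaCl libraries held 41701300, 40334700 and 40346700 counted reads, and the high-NaCl libraries 42021300, 46861500 and 40101900, each to 6 digits. Expression values in CPM (counts-per-million, scaled between libraries) are means ± SD with n = 3, low-NaCl against high-NaCl, and log2 fold changes are low-NaCl minus high-NaCl ± SE. Adjusted p-values of genes are from edgeR, those of gene lists from camera, and values in parentheses after an alternative are adjusted p-values too. The counts come from annotated exons in build mm10, matched to genes of GENCODE. The GENCODE gene spans, which can be wider than the counted exons, place Scnn1a on chromosome 6 (125320659 to 125344943), Scnn1g on chromosome 7 (121734479 to 121768475), Sgk1 on chromosome 10 (21882184 to 21999903), Aqp2 on chromosome 15 (99579055 to 99584547) and Fosb on chromosome 7 (19302696 to 19310051).

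The comparison of the diets asks which transcripts of collecting duct cells differ between a sodium intake that raises aldosterone and one that lowers it. On the low-NaCl diet, the lists of genes of the unfolded protein response and of markers of intercalated cells lay higher by camera, a test of gene lists, and those of immediate early genes and of markers of principal and connecting tubule cells lay lower. Those calls used a preset correlation between genes. With an estimated correlation no list fixed beforehand passed (adjusted p of these from 0.103 to 0.321), and with a lane term the shared and type A intercalated lists did not. Another list test, fry, passed the unfolded protein response, immediate early, principal cell and connecting tubule lists. It passed no intercalated list (adjusted p by fry 0.0664 to 0.157). The smallest p-values belonged to Manf, Sec14l1 and Pappa2 among the higher genes and to Fosb, Ier2 and Fos among the lower ones. Of 10562 genes tested, 182 were higher and 184 lower, of which 122 and 138 differed at least 2-fold. The 3 libraries of a diet lay apart from those of the other in all 366 called genes and in 2524 tested genes. A call with 3 libraries per diet makes such separation likely. Chance would separate 10% of genes on average, but genes vary together, and separation was not counted for other splits of the libraries. Lane 1 of the sequencer held library 1 of each diet, lane 2 low-NaCl libraries 2 and 3, and lane 3 high-NaCl libraries 2 and 3. With lane as a term, which leaves the diet difference to lane 1 alone, the counts of genes higher on the low-NaCl diet and of genes lower on the low-NaCl diet were 1 and 2. They were 292 and 186 without low-NaCl library 1, 39 and 36 without low-NaCl library 2, 59 and 76 without low-NaCl library 3, 67 and 95 without high-NaCl library 1, 256 and 253 without high-NaCl library 2, and 34 and 53 without high-NaCl library 3.

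Transcripts of the 3 subunits of the epithelial sodium channel (ENaC) had log2 fold changes of both signs. Scnn1g, the gamma subunit, was 2.42-fold lower on the low-NaCl diet (302 ± 66.2 against 731 ± 121 CPM, log2 fold change -1.27 ± 0.20, adjusted p = 0.0128). Scnn1a, the alpha subunit and a textbook aldosterone target, measured 1900.0 ± 285 against 1288 ± 242 CPM, with a log2 fold change of 0.56 ± 0.19 that did not pass (adjusted p = 0.154). Scnn1b, the beta subunit, had a log2 fold change of -1.72 ± 0.56 (adjusted p = 0.134), with only 5.97% of its exonic bases countable, and of -0.68 without high-NaCl library 2. The ratio of Scnn1a to Scnn1g CPM, chosen after the values were seen, was 6.34 ± 0.437 on the low-NaCl and 1.8 ± 0.48 on the high-NaCl diet (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Within lane 1 it was 6.71 against 2.19. Of 7 tested genes of ENaC and its proteases 1 fell and none rose. Over all genes 1 rose and 2 fell by DESeq2, and 2 rose and 1 fell with sample weights or the replicate block. Adjusted over the list alone 2 fell and 2 rose, and the list did not pass camera (adjusted p = 0.527). The Scnn1g call ended without low-NaCl library 2 (0.0684) and with a lane term (0.243).

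**Figure D1:**
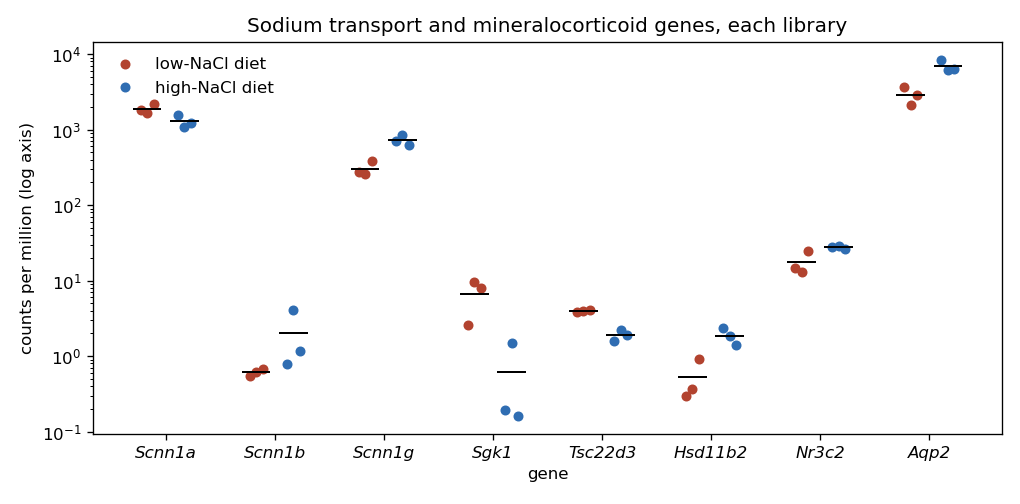
CPM on a log axis for 8 genes of sodium transport and mineralocorticoid action, with each point a library and each black line the mean of 3 libraries per diet. In each of the 8 genes the 3 low-NaCl libraries lie apart from the 3 high-NaCl libraries. Scnn1g and Aqp2 were called lower and Sgk1 and Tsc22d3 higher on the low-NaCl diet. Scnn1a, higher at 1900.0 against 1288 CPM, did not pass the test, nor did Scnn1b, Hsd11b2 and Nr3c2, which lie lower.

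Sgk1, a kinase induced by aldosterone that holds ENaC at the cell surface, was 10.2-fold higher on the low-NaCl diet (6.74 ± 3.68 against 0.621 ± 0.771 CPM, adjusted p = 0.0417). High-NaCl library 2 held 1.51 CPM of Sgk1 against 0.193 and 0.16 CPM in the others. The log2 fold change was 3.35 ± 0.75 with that library and 5.24 without it. Tsc22d3, which encodes the steroid-induced protein GILZ, was 2.09-fold higher (3.95 ± 0.112 against 1.89 ± 0.315 CPM, adjusted p = 0.0326). Of 12 tested aldosterone targets these 2 rose and none fell, over all genes and adjusted over the list alone. Klf9, a steroid-responsive transcription factor, had a log2 fold change of 0.55 ± 0.20 (adjusted p = 0.173). The list lay higher by camera (adjusted p = 0.00827), with an adjusted p of 0.192 with an estimated correlation, and its median log2 difference was 0.43 within lane 1 and 0.32 over all libraries (0.55 with no filter). Only 38.2% of the exonic bases of Sgk1 and 44.8% of those of Tsc22d3 could be counted. The Sgk1 call ended without low-NaCl library 2 or 3 or high-NaCl library 1 or 3 (0.0958 to 0.227) and with total-count scaling, no filter or limma-voom (0.0645 to 0.298) and with a lane term (0.329). The Tsc22d3 call ended without low-NaCl library 2 or 3 or high-NaCl library 1 or 3 (0.0844 to 0.123) and with total-count scaling (0.0772) and with a lane term (0.285). The list call ended with a lane term (0.0563) or among genes at least 50% countable (0.0944).

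Glucocorticoid response genes, a list that shares Sgk1 and Tsc22d3 with the aldosterone targets, included 3 that rose and none that fell among 12 tested, and 5 that rose adjusted over the list alone. The third was Lcn2, a secreted siderophore-binding protein also used as a marker of tubular injury, at 134 ± 52.1 against 30.4 ± 1.21 CPM (4.39-fold higher, adjusted p = 0.00658). Camera gave the list an adjusted p of 0.00453, and of 0.282 with an estimated correlation. The call ended with sample weights (0.0523) or with only genes at least 50% countable (0.099). The list's median log2 difference was 0.55 within lane 1 and 0.57 over all libraries (0.31 with the CPM filter and 0.10 with only genes at least 50% countable). Regulators of mineralocorticoid action and WNK kinases lay lower as a list. Nr3c2, the mineralocorticoid receptor, measured 17.5 ± 6.33 against 27.7 ± 1.4 CPM (adjusted p = 0.152). Hsd11b2, the enzyme that keeps glucocorticoids from that receptor, had a log2 fold change of -1.80 ± 0.44 (adjusted p = 0.0573) with 2.27% of its exonic bases countable, and of -2.47 without low-NaCl library 3. None of the 7 tested members passed over all genes, 4 fell adjusted over the list alone, and camera gave an adjusted p of 0.00827, or of 0.282 with an estimated correlation. That list call ended without low-NaCl library 1 (0.0566), and only 2 of its members were at least 50% countable, too few to test. Its median log2 difference was -0.58 within lane 1 and -0.53 over all libraries (-0.23 with no filter). Of 5 tested genes of the Na,K-ATPase list none passed over all genes, and 1, Fxyd4, fell adjusted over the list alone. Fxyd4, the only member below 0, had a log2 fold change of -1.74 ± 0.51. Only 0.40% of its exonic bases were countable, and it measured 0.22 against 0.75 CPM. The list median was 0.25 (0.09 with sample weights and 0.07 without low-NaCl library 1) and the mean -0.16, and camera gave 0.706.

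Principal cell markers lay lower on the low-NaCl diet as a list. Aqp2, the vasopressin-regulated water channel, was 2.43-fold lower (2869.5 ± 744 against 6964 ± 1176 CPM, adjusted p = 0.0222), and Aqp3, a basolateral water channel, 2.41-fold lower (874 ± 159.8 against 2102 ± 518 CPM, adjusted p = 0.0193). With Scnn1g these made 3 that fell and none that rose among 9 tested markers, and 7 fell adjusted over the list alone. Of 3 tested connecting tubule markers 2 fell, over all genes and adjusted over the list alone: Calb1, a calcium-binding protein (2.56-fold lower, adjusted p = 0.00658), and Trpv5, a calcium channel (2.7-fold lower, adjusted p = 0.0417). Klk1, which encodes tissue kallikrein, had a log2 fold change of -0.16 ± 0.20 (adjusted p = 0.715). Camera gave adjusted p-values of 5.15e-09 and 9.57e-05 for these lists, and of 0.103 and 0.112 with an estimated correlation. Their median log2 differences were -1.15 and -0.90 within lane 1, and -1.28 and -1.36 over all libraries. The call of Aqp2 ended without low-NaCl library 2 or 3 or high-NaCl library 1 or 3 (0.0513 to 0.0932), and that of Aqp3 without low-NaCl library 2 (0.0887) and with total-count scaling (0.0545). That of Trpv5 ended without low-NaCl library 1 or 2 or high-NaCl library 1, 2 or 3 (0.0605 to 0.162) and with total-count scaling, no filter or only genes at least 50% countable (0.0518 to 0.146), while Calb1 was called without each library in turn.

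Markers of intercalated cells, the acid-base transporting cells of the collecting duct, lay higher as lists. Foxi1, the transcription factor that specifies them, was 2.64-fold higher on the low-NaCl diet (389 ± 121 against 147 ± 15.4 CPM, adjusted p = 0.0128). Of 8 tested members of the shared intercalated list 4 rose and none fell, and 5 rose adjusted over the list alone. Besides Foxi1, those that rose over all genes were the proton pump subunits Atp6v1g3 (2.74-fold) and Atp6v0d2 (2.57-fold) and the carbonic anhydrase Car12 (2.03-fold). The ammonia transporter Rhcg, at 1731 ± 445 against 1900.0 ± 372 CPM, did not pass (adjusted p = 0.802). Of 4 tested type A markers 2 rose, the anion exchanger Slc4a1 (3.29-fold, adjusted p = 0.0448) and Adgrf5 (7.21-fold, adjusted p = 0.0367), and all 4 rose adjusted over the list alone. Adgrf5 measured 3.32 ± 2.47 against 0.467 ± 0.179 CPM. Only 12.1% of the exonic bases of Adgrf5 and 13.8% of those of Car12 could be counted. Of 6 tested type B markers 2 rose, the transcription factor Hmx2 (2.62-fold, adjusted p = 0.00658) and the oxoglutarate receptor Oxgr1 (2.53-fold, adjusted p = 0.0203), and all 6 rose adjusted over the list alone. Slc26a4, the anion exchanger pendrin, measured 807 ± 323 against 382 ± 18.3 CPM (adjusted p = 0.0647). Camera adjusted p-values were 1.13e-05, 5.10e-05 and 5.15e-09 for the shared, type A and type B lists, and 0.321, 0.282 and 0.192 with an estimated correlation. Median log2 differences were smaller within lane 1, at 0.51, 0.62 and 0.74, than over all libraries, at 1.03, 1.53 and 1.24, and with a lane term the shared and type A lists did not pass (0.218 and 0.167). Gene calls ended for Foxi1 without high-NaCl library 3 (0.0737), Atp6v1g3 without low-NaCl library 2 or high-NaCl library 1 or 3 (0.0624 to 0.0919), Atp6v0d2 without low-NaCl library 2 or high-NaCl library 1, 2 or 3 (0.0619 to 0.0879), Car12 without low-NaCl library 2 or 3 or high-NaCl library 3 (0.0625 to 0.0899) and Oxgr1 without low-NaCl library 2 or high-NaCl library 1 or 3 (0.0669 to 0.0879). The call of Slc4a1 ended without low-NaCl library 2 or 3 or high-NaCl library 1, 2 or 3 (0.104 to 0.206) and with total-count scaling, no filter, the CPM filter, limma-voom, sample weights, the replicate block or only genes at least 50% countable (0.0504 to 0.257). That of Adgrf5 ended without low-NaCl library 2 or 3 or high-NaCl library 1, 2 or 3 (0.104 to 0.137) and with total-count scaling, no filter, limma-voom, sample weights or each transcript alone (0.0547 to 0.121), and without low-NaCl library 3 the log2 fold change of Adgrf5 was 2.15 against 2.85 ± 0.61.

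Immediate early genes, which are transcribed within minutes of a stimulus and also during tissue dissociation, mostly lay lower on the low-NaCl diet. The AP-1 subunit genes Fosb (7.46-fold lower, 10.7 ± 1.85 against 79.6 ± 11.2 CPM, adjusted p = 0.000223) and Fos (5.59-fold lower, 85.4 ± 6.33 against 478 ± 163 CPM, adjusted p = 0.0036) and the gene Ier2 (4.05-fold lower, adjusted p = 0.000574) had the smallest p-values of the list, and Junb was 3.08-fold lower (adjusted p = 0.00658). In all, 8 of 12 tested members fell and 1 rose, with the same counts adjusted over the list alone. Without each library 5 to 7 fell, with total-count scaling 5, with exact intron matches 4 of 8, and with a lane term 1. The member that rose was Ier3 (2.34-fold, adjusted p = 0.0152). Camera gave the list an adjusted p of 3.44e-21, and of 0.103 with an estimated correlation, and its median log2 difference was -1.67 within lane 1 and -1.77 over all libraries (-1.11 with exact intron matches only). Of 8 tested heat shock genes 1 rose, the mitochondrial co-chaperonin Hspe1 (1.52-fold, adjusted p = 0.0448), and none fell; adjusted over the list alone 2 rose and 1 fell, and camera gave 0.215. The Hspe1 call ended without low-NaCl library 1, 2 or 3 or high-NaCl library 1, 2 or 3 (0.0523 to 0.183) and with total-count scaling, limma-voom or each transcript alone (0.0506 to 0.0576).

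Genes of the unfolded protein response, many of them chaperones of the endoplasmic reticulum, lay higher on the low-NaCl diet as a list. Manf rose 4.52-fold (30.7 ± 7.17 against 6.79 ± 0.623 CPM, adjusted p = 0.00273) with 13.0% of its exonic bases countable, Creld2 3.58-fold (193 ± 48.4 against 54.0 ± 6.02 CPM, adjusted p = 0.0036), Sdf2l1 3.65-fold (adjusted p = 0.00658) and the disulfide isomerase Pdia4 2.75-fold (adjusted p = 0.00743). Hspa5 and Herpud1 of the list had no counted read and Xbp1 too few to test (3.13%, 0.16% and 1.04% of exonic bases countable). Of 11 tested members 7 rose and none fell, and 10 rose adjusted over the list alone. Without each library 4 to 7 rose, and with a lane term none. Camera gave an adjusted p of 2.78e-22, and of 0.112 with an estimated correlation. The median log2 difference was 0.94 within lane 1 and 0.78 over all libraries. The Pdia4 call ended without high-NaCl library 3 (0.0506).

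**Figure D2:**
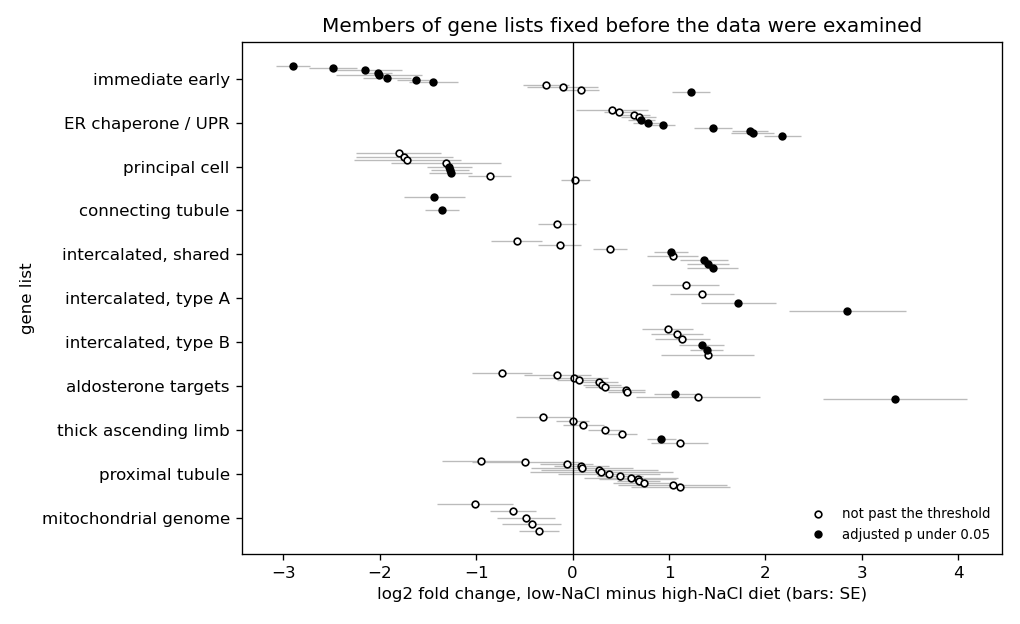
Log2 fold changes, low-NaCl minus high-NaCl diet, of the tested members of 11 gene lists, with bars for the SE, filled points for an adjusted p under 0.05 and open points for members that did not pass. Immediate early genes lie mostly left of 0 (8 of 12 fell) and unfolded protein response genes right of 0 (7 of 11 rose).

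Several genes with the smallest p-values belonged to none of those lists. On the low-NaCl diet Pappa2, a protease that cleaves binding proteins of insulin-like growth factors, was 9.81-fold higher (8.85 ± 4.05 against 0.901 ± 0.118 CPM, adjusted p = 0.0036), and the Wnt ligand Wnt10a 5.24-fold higher (49.5 ± 13.0 against 9.47 ± 2.44 CPM, adjusted p = 0.0036). The secreted Wnt-binding protein gene Sfrp1 rose 2.53-fold, Sec14l1 3.18-fold, the bradykinin receptor gene Bdkrb2 3.57-fold and the arginase gene Arg2 3.61-fold, with 20.1% of the exonic bases of Arg2 shared with another gene. Atp12a, a catalytic subunit of the H,K-ATPase, which exchanges protons for potassium, was 14.5-fold lower (0.64 ± 0.162 against 9.29 ± 5.05 CPM, adjusted p = 0.0036). It was the 1 that fell of 7 tested potassium channel and H,K-ATPase genes, of which none rose. Adjusted over the list alone 2 fell and 1 rose, and camera gave 0.291. The median log2 fold change of that list was 0.03 (0.01 to 0.12 without each library) and the mean -0.50. With the CPM filter the median was -0.09 and with sample weights -0.05. Ndrg1 was 2.88-fold lower (729.8 ± 97.1 against 2103 ± 162 CPM), Nudt11 3.57-fold, the meiotic cohesin gene Rec8 2.53-fold, Cyp2j11 3.06-fold and Rasl11a 3.48-fold. The 20 genes named for their small p-values were called in every alternative with gene values that tested them, except the lane term, with which only Fosb of 44 called named genes still passed (0.0219). Single genes were not compared without the libraries above 25% mitochondrial counts.

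Few markers of other tubule segments passed. Slc12a1, the Na-K-Cl cotransporter of the thick ascending limb, was 1.89-fold higher on the low-NaCl diet (61.6 ± 3.55 against 32.6 ± 5.72 CPM, adjusted p = 0.0159), but its log2 fold change was -0.10 when only transcripts with matching introns were summed, and its call ended without low-NaCl library 2 or 3 (0.0529 to 0.053). It was the 1 that rose of 7 tested thick limb markers, of which none fell, and 3 rose adjusted over the list alone. Camera gave 0.0111, or an adjusted p of 0.496 with an estimated correlation. The call ended with sample weights (0.194), with exact intron matches only (0.193), without low-NaCl library 1 (0.1), without high-NaCl library 2 (0.256) or with a lane term (0.0563), and only 2 of its members were at least 50% countable, too few to test. The thick limb median was 0.30 within lane 1 and 0.33 over all libraries (0.11 with exact intron matches only, 0.07 with only genes at least 50% countable and 0.18 without high-NaCl library 2). None of 15 proximal tubule genes passed, with Aqp1 at 2594 ± 871 against 1549 ± 616 CPM; camera gave 0.262, and 0.00699 in the higher direction without low-NaCl library 1 but 0.0418 in the lower direction with a lane term. None of 4 distal convoluted tubule genes passed, 1 rose adjusted over the list alone, and camera gave 0.2. Of 14 immune cell genes 1 had enough counts to test. The 6 tested endothelial genes summed to 22.7 CPM on the low-NaCl and 25.2 CPM on the high-NaCl diet. No member passed over all genes among 6 endothelial (camera adjusted p = 0.143, 1 lower adjusted over the list alone), 6 stromal (0.185), 4 podocyte (0.281), 6 urothelial and papillary (0.291) or 4 erythroid genes (0.352). Without 1 library some of these lists passed: endothelium without low-NaCl library 1 or 2 (0.009 and 0.0395), stroma without low-NaCl library 1 (0.00808), podocytes without low-NaCl library 2 (0.0117) and erythroid genes without low-NaCl library 3 or high-NaCl library 3 (0.00192 and 0.0385). Median log2 differences within lane 1 were -0.06 for endothelial, 0.19 for stromal, -1.55 for podocyte, -0.94 for urothelial and papillary and 3.12 for erythroid genes. Over all libraries they were -0.43, 0.61, -0.63, -0.56 and 1.17. Lists that did not pass could thus also differ widely within lane 1.

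The mitochondrial share of counts was 21.1 ± 0.665% on the low-NaCl and 26.8 ± 4.33% on the high-NaCl diet (two-sided exact permutation p = 0.1, the smallest possible), and within lane 1 21.8% against 29.9%. High-NaCl libraries 1 and 3 held 29.9% and 28.7%, and high-NaCl library 2 21.9%. Without libraries above 25%, a choice made after the values were seen, 31 genes higher on the low-NaCl diet and 92 genes lower on the low-NaCl diet were called, the lone high-NaCl library being assumed to vary like the others. Counts at the ribosomal RNA locus made up 0.721 ± 0.0753% and 0.978 ± 0.163% (two-sided exact permutation p = 0.1). None of 5 tested mitochondrial genes passed, with a median log2 difference of -0.69 within lane 1 and -0.49 over all libraries (-0.27 without high-NaCl library 1 and -0.77 without high-NaCl library 2). Their list lay lower by camera (adjusted p = 0.0306), with an adjusted p of 0.521 with an estimated correlation. That call ended with only genes at least 50% countable (0.0771), without low-NaCl library 2 (0.0771), without high-NaCl library 1 (0.214) or without high-NaCl library 3 (0.121). No member passed among 32 nuclear genes of oxidative phosphorylation (camera 0.588) or 38 ribosomal protein genes (0.256, and 0.0255 without low-NaCl library 1). Between the 2 libraries closest in mitochondrial share across diets, low-NaCl 1 and high-NaCl 2, the median log2 difference was -2.10 for immediate early genes, 0.87 for the unfolded protein response, -1.56 for principal cell markers, and 0.57, 1.36 and 0.68 for shared, type A and type B intercalated markers.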

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

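The settings that took each transcript alone, exact intron matches, genes at least 50% countable, or libraries of low mitochondrial share were chosen after the data were seen. The 182 genes higher on the low-NaCl diet and 184 genes lower on the low-NaCl diet became 81 and 55 with total-count scaling, 408 and 448 by DESeq2, 593 and 603 by limma-voom with sample weights, 1 and 2 with a lane term, which has few residual degrees of freedom, and 31 and 92 without libraries above 25% mitochondrial counts, 88 of them shared; with no filter the lower count was 280. Leaving out each library, with fewer samples, gave 34 to 292 and 36 to 253. Across diets, correlations of same-numbered libraries were 0.19, 0.27 and -0.07, and those of other pairs -0.29 to 0.10. These are too few to decide whether replicate numbers pair the samples. With the numbers as a block the counts were 465 and 447. In the other settings both counts stayed within 1.5 times. Every called gene that was tested kept its direction in each setting that tested genes, which separated diets make nearly certain, except 2 of 340 with exact intron matches; directions without the high-mitochondrial libraries were not counted. The 15 lists past the threshold became 8 among genes at least 50% countable (5 of the 15 lost and 2 with too few members to test), 5 by fry and 0 by camera with an estimated correlation (7 at an unadjusted p under 0.05), 14 to 16 without each library (up to 3 of the 15 lost, without low-NaCl library 1) and 14 with a lane term (6 of the 15 lost). Of 252 unmatched identifiers tested alone edgeR called 0, with 34 at an unadjusted p under 0.05.

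Of 144 named genes 44 were called, and 153 of their 865 alternative values kept their direction but were not past the threshold: 43 with the lane term, 20, 14 and 4 without low-NaCl libraries 2, 3 and 1, 19, 12 and 7 without high-NaCl libraries 3, 1 and 2, 11 with total-count scaling, and 7 or fewer elsewhere. Log2 fold changes that turned sign belonged to 1 called gene, Slc12a1 (-0.10 with exact intron matches, not past the threshold), and to uncalled ones; the cause was not tested. Stk39 was 0.24 with exact intron matches. With a lane term Upk1b was -3.32, Tagln -0.75, Wt1 -2.54, Slc6a6 -0.41, Usp18 0.14 and Ccl2 -1.42. By limma-voom Trpm7 was 0.0034, Upk1b -0.10, H2-Aa 0.035 and Wt1 -0.016, and with sample weights Trpm7 was 0.80, Flt1 -0.58, H2-Aa 0.87, Hba-a1 -0.48, Hbb-bs -1.77 and Hbb-bt -1.34. H2-Aa was 0.053 with total-count scaling and 0.031 with the block. Leaving out each library gave Trpm7 -0.67 to 0.28, Upk3a -2.43 to 0.41, Slc14a2 -1.10 to 0.12, Flt1 -0.80 to 0.69 and H2-Aa -0.39 to 0.41. Among the 100 uncalled named genes, 99 alternative values kept their direction and passed the threshold. Depth limits genes with few countable bases, such as Hsd11b2 (2.27%) and Scnn1b (5.97%).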

Other observations

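The tests of cell type share, lane, dissociation and shared exons, and the lists of tubulins, macula densa, antigen presentation and Notch genes, were chosen only after the results had been seen; the counts over other splits were planned. These 4 lists were written from called genes and are not independent evidence of a direction. Their camera p-values were adjusted over these 4 lists alone and reflect how the lists were chosen, so they do not test a shift. They cannot be compared with the p-values of the lists fixed beforehand, with an estimated correlation either. A lane term leaves 1 library per diet to compare, so it does not part diet from variation between libraries. It also leaves few residual degrees of freedom. Of 10 tested tubulin genes 5 rose on the low-NaCl diet and none fell (8 rose adjusted over the list alone), led by Tubb2b (145 ± 35.6 against 66.1 ± 10.5 CPM, adjusted p = 0.0191), with a camera adjusted p of 3.65e-08, and of 0.13 with an estimated correlation. Of 8 listed genes known from macula densa cells, the salt sensors of the thick ascending limb, 5 were tested and all 5 rose. They were Pappa2, Wnt10a, Slc12a1, the vasopressin receptor gene Avpr1a (113 ± 43.1 against 44.0 ± 2.19 CPM, adjusted p = 0.0231) and the cyclooxygenase gene Ptgs2 (0.982 ± 0.558 against 0.113 ± 0.0953 CPM, adjusted p = 0.0346). Slc12a1, with 24.5% of its exonic bases countable, turned sign with exact intron matches. Whether these transcripts came from macula densa cells was not tested. The macula densa list had a camera adjusted p of 3.94e-16, and of 0.00639 with an estimated correlation. The Ptgs2 call ended without low-NaCl library 2 or 3 or high-NaCl library 2 or 3 (0.0533 to 0.135) and with limma-voom (0.0556), and its log2 fold change was 3.17 ± 0.66, or 4.04 without high-NaCl library 1. Of 11 tested antigen presentation genes 3 fell and none rose (8 fell adjusted over the list alone), the immunoproteasome genes Psmb9 (2.6-fold) and Psmb8 (1.66-fold) and the class I gene H2-T23 (1.47-fold), with a camera adjusted p of 7.72e-07, and of 0.0363 with an estimated correlation. Of 11 tested Notch genes the ligands Dll1 (2.67-fold) and Dll4 (2.38-fold) rose and the targets Nrarp (2.08-fold) and Hes1 (1.77-fold) fell, and camera gave 0.29.

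Of 9 tested cell cycle genes 2 fell, Ccna2 (3.14-fold lower, adjusted p = 0.0154) and Cdk1 (3.25-fold lower, adjusted p = 0.0221), and none rose; 4 fell adjusted over the list alone. Camera gave 3.57e-05, or an adjusted p of 0.192 with an estimated correlation. The median log2 difference was -0.12 within lane 1 against -1.35 over all libraries, and with a lane term the list did not pass (0.167). The Ccna2 call ended without low-NaCl library 2 or 3 or high-NaCl library 3 (0.053 to 0.0734). That of Cdk1 ended without low-NaCl library 2 or 3 or high-NaCl library 3 (0.0649 to 0.0932) and with total-count scaling (0.0545). Of 10 tubular injury genes 2 rose, Lcn2 and Cdkn1a (3.11-fold, adjusted p = 0.0431), none fell, and 3 rose adjusted over the list alone. Camera gave 0.0078, or an adjusted p of 0.343 with an estimated correlation. The median was -0.0025 within lane 1 against 0.94 over all libraries. The call ended with limma-voom (0.0661), with only genes at least 50% countable (0.102), without high-NaCl library 2 (0.0546) or with a lane term (0.978). The Cdkn1a call ended without low-NaCl library 1, 2 or 3 or high-NaCl library 1, 2 or 3 (0.0517 to 0.206) and with total-count scaling, limma-voom, sample weights or each transcript alone (0.0518 to 0.0643). None of 14 cholesterol synthesis genes passed; camera gave 0.0111, or an adjusted p of 0.485 with an estimated correlation. Its call ended with only genes at least 50% countable (0.099) or without low-NaCl library 1 (0.116), and its median was 0.51 within lane 1 and 0.37 over all libraries. Of 7 genes of prostaglandin, endothelin and nitric oxide signalling Ptgs2 rose and the receptor gene Ptger1 fell, 45.3% of whose exonic bases lie in another gene; adjusted over the list alone 1 rose and 2 fell (camera 0.504). The Ptger1 call ended without low-NaCl library 2 or 3 or high-NaCl library 3 (0.0823 to 0.0954) and with total-count scaling (0.0576). Ifit3 rose as 1 of 9 interferon response genes (1.64-fold; adjusted over the list alone 1 rose and 1 fell; camera 0.54). Its call ended without low-NaCl library 1, 2 or 3 or high-NaCl library 1 or 3 (0.0682 to 0.159) and with upper-quartile scaling, total-count scaling, limma-voom or each transcript alone (0.0515 to 0.0992). No member passed among 10 circadian clock genes (camera 0.575; adjusted over the list alone 1 rose and 1 fell), 8 tight junction genes (0.493; 1 fell adjusted over the list alone), 6 osmotic stress genes (0.238), 17 genes of glycolysis and hypoxia (0.268) or 4 renin-angiotensin genes (0.625). Median and mean differed in sign for the prostaglandin list (-0.16 and 0.24) and the clock list (0.01 and -0.09). Without each library these medians were -0.43 to 0.01 and -0.34 to 0.24.

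The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 366 genes by edgeR and 1 of the 10 splits called as many; the highest of the others called 0, with 102 to 2037 genes at an unadjusted p under 0.05 against 1934 in the real one. The real split shifted 15 lists by camera at the preset correlation, 1 split shifted as many, and the highest of the others shifted 13. The split with 2037 genes set low-NaCl library 1 and high-NaCl libraries 1 and 3, with 13795, 13310 and 13961 genes with a count, against the others, with 14323, 14308 and 14592. It points to a structure of the samples besides diet.

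As lists, principal and connecting tubule markers lay lower and intercalated markers higher on the low-NaCl diet. A loss of principal cells alone would raise markers of every other cell type alike. Over all libraries 18 intercalated markers lay above 26 thick limb, distal convoluted and proximal markers by a median log2 difference of 0.86 (two-sided permutation p over genes = 0.00013). Such a p treats markers that vary together as independent and does not measure the spread between libraries. Per library that difference was 0.03, 0.26 and 0.82 on the low-NaCl and -0.33, -0.28 and -0.51 on the high-NaCl diet. Within lane 1 the diets differed by 0.35, and 2 libraries of the same diet and lane by up to 0.56, so a loss of principal cells stays open. A larger share of intercalated cells would raise type A and type B markers alike. Their medians differed by 0.29 (two-sided exact permutation p over 4 and 6 genes = 0.0714), a p that does not measure the spread between libraries. Of 13 well counted markers 2, Rhcg and Rhbg, lay below 0, so by the bound set a larger share of intercalated cells stays open. Whether transcripts of these 2 come from intercalated cells alone was not tested. With a lane term the median log2 change of the principal and connecting tubule markers was -1.02 (median SE of members 0.37), against -1.29 (SE 0.23) without it. Of 5 called members 0 passed with it. Within lane 1 the median difference was -1.02, while 2 libraries of the same diet and lane differed by up to 0.40. The change was smaller, the SE larger and the residual degrees of freedom fewer, and which of these ended the gene calls was not tested. Both lists still passed camera at the preset correlation (0.000351 and 0.00451), but not with an estimated one (0.518 for each), with which they did not pass without the lane term either (0.103 and 0.112). The lane term rests on the same 2 libraries as the difference within lane 1, so it adds no separate support. That difference, of 1 library against 1, exceeded those of the pairs low-NaCl 2 and 3 and high-NaCl 2 and 3. By it alone lane as the whole cause is argued against for these, but variation between libraries is not. With a lane term the median log2 change of the shared and type A intercalated markers was 0.62 (median SE of members 0.34), against 1.26 (SE 0.26) without it. Of 6 called members 0 passed with it. Within lane 1 the median difference was 0.62, while 2 libraries of the same diet and lane differed by up to 0.61. Neither list passed camera with the lane term (0.218 and 0.167), so lane stays open for these. With a lane term the median log2 change of the type B markers was 0.74 (median SE of members 0.29), against 1.24 (SE 0.27) without it. Of 2 called members 0 passed with it. Within lane 1 the median difference was 0.74, while 2 libraries of the same diet and lane differed by up to 0.53. That list passed camera at the preset correlation with the lane term (0.0163; 0.623 with an estimated one), but its difference within lane 1 was only 1.38 times the largest between libraries of the same diet and lane, short of the 2 times set for excluding lane, so lane stays open for it too. A change of expression within cells by diet is a candidate explanation that was not tested.

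Of 12 immediate early genes 8 fell and 1 rose on the low-NaCl diet. With a lane term the median log2 change of the list was -1.71 (median SE of members 0.26), against -1.77 (SE 0.24) without it. Of 9 called members 1 passed with it. Within lane 1 the median difference was -1.67, while 2 libraries of the same diet and lane differed by up to 0.27. The change was about as large, while the SE was larger and the residual degrees of freedom fewer; what ended the gene calls was not tested. With the lane term the list passed camera at the preset correlation (5.97e-15) but not with an estimated one (0.518), with which it did not pass without the lane term either (0.103). The lane term rests on the same 2 libraries as the difference within lane 1, so it adds no separate support. That difference, of 1 library against 1, exceeded those of the pairs low-NaCl 2 and 3 and high-NaCl 2 and 3. By it alone lane as the whole cause is argued against, but variation between libraries is not. Loss of a cell type that holds these transcripts stays open: their median lay -0.48 from that of principal and connecting tubule markers (two-sided permutation p over genes = 0.0708). A p over genes does not measure the spread between libraries. A harsher or longer dissociation of the high-NaCl samples could raise them, and the heat shock list, also induced by dissociation, had a median log2 change of 0.27 (0.17 with no filter, 0.17 with the CPM filter, 0.43 with sample weights and 0.43 without high-NaCl library 2), which decides nothing since handling times are not in the labels. An effect of diet stays open as well and was not tested apart from these.

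Of 11 genes of the unfolded protein response 7 rose on the low-NaCl diet. Reads lost in exons shared by isoforms are argued against, since the 10 members with at least 50% of their exonic bases countable had a median log2 change of 0.75 and passed camera among such genes at the preset correlation (adjusted p = 5.19e-16), though not with an estimated one (0.141). With a lane term the median log2 change of the list was 0.94 (median SE of members 0.30), against 0.78 (SE 0.18) without it. Of 7 called members 0 passed with it. Within lane 1 the median difference was 0.94, while 2 libraries of the same diet and lane differed by up to 0.36. The change was about as large, while the SE was larger and the residual degrees of freedom fewer; what ended the gene calls was not tested. With the lane term the list passed camera at the preset correlation (1.83e-13) but not with an estimated one (0.518), with which it did not pass without the lane term either (0.112). The lane term rests on the same 2 libraries as the difference within lane 1, so it adds no separate support. That difference, of 1 library against 1, exceeded those of the pairs low-NaCl 2 and 3 and high-NaCl 2 and 3. By it alone lane as the whole cause is argued against. A response to diet is a candidate explanation that was not tested apart from variation between libraries.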
